A study of Mus musculus with 12 samples.

How the data were processed

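Chromatin immunoprecipitation with sequencing was run on lineage-negative, cKit-positive bone marrow cells, a fraction rich in hematopoietic stem and progenitor cells, from C57BL/6 mice. Per the labels, the cells were sorted 4 days after an injection of poly(I:C), which induces the Mx1Cre recombinase through the interferon response and so deletes the floxed Ints11 gene; WT littermates received it too. Ints11 encodes the catalytic subunit of Integrator, the complex that cleaves nascent small nuclear and other RNAs. The 12 libraries were H3K27me3 (4 libraries), H3K4me3 (4 libraries) and input (4 libraries), with 2 mice per genotype, named WT_407, WT_409, KO_399 and KO_401 after the numbers in the labels, which were read as mice. Chromatin was fixed in 1% formaldehyde and sheared to 100 to 300 bp, and reads were 75 bp long, per the labels.

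Per the submitters' processing notes, FastQC, Trim Galore, Bowtie2, SAMtools, MACS2 and deepTools were used with the genome build mm10, and no version is named. Each of the 8 immunoprecipitated libraries had its own peak list in narrowPeak layout, so peaks were called per library and not on pooled mice. No list of the input libraries was used here, and whether input served as the control of the peak caller is not given in the sources used here. In each list the deposited score is a whole number per peak, the deposited fold is the ratio of the pileup at the summit to the expected background, and the deposited −log10 values are of the p-value and of the q-value. These are the authors' values per peak, and they were used only to describe, rank or filter peaks within a list. Every deposited fold was above 5, and the peak names skipped numbers. The lists were thus filtered at a fold of 5 after calling, a step that no label records. Set against the highest peak number in each name column, 24.8%, 29.8%, 36.5% and 27.0% of H3K27me3 peaks were kept in WT_407, WT_409, KO_399 and KO_401. For H3K4me3 the share was 66.7% to 78.0%. A site without a listed peak in a library may therefore have had a called peak there under that fold. H3K27me3 forms broad domains, and the narrow layout breaks a domain into several peaks, so covered length is given beside every number of peaks.

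Read totals were not part of the files. The pileup and the background at each summit were recovered from the deposited fold, taken as (pileup + 1) / (background + 1), and from the deposited −log10 p, taken as the Poisson chance of more reads than the pileup. A whole-number pileup solved both within 0.001 of −log10 p for 100% of the summits of each library. The most frequent background of a library is its genome-wide value, which is proportional to the depth used in peak calling at a given fragment length. The labels give no fragment length for single libraries beyond the range of shearing. For H3K27me3 it was 3.09 reads per position in WT_407, 3.16 in WT_409, 3.30 in KO_399 and 3.67 in KO_401. For H3K4me3 it was 2.23, 1.94, 2.65 and 1.93 in the same order. A fold of 5 then needed 19.5 to 22.4 reads at a summit for H3K27me3 and 13.7 to 17.2 for H3K4me3. If the caller scaled a library down to its input, these are depths after scaling.

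Gene positions came from a RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The match was checked by the share of genes with an H3K4me3 peak within 1 kb of a gene end. It was 57.0% to 59.7% across libraries, against 12.8% to 14.4% with all coordinates moved by 100 kb. The table gives the span of each gene but no strand and no transcripts, so the start site could not be told from the other end. A gene was therefore counted as having a peak at the promoter when a peak of at least 1 bp lay within 2 kb of either end of its span. This replaced the start sites of the planned rule.

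Peaks of all 4 libraries of a mark were merged into regions where they overlapped by 1 bp or touched, and a library had a region when its peaks covered at least 1 bp of it. Regions and genes were then sorted by their libraries: in both WT and neither KO library (WT only), in both KO and neither WT library (KO only), or in all 4. Overlap of libraries was measured by the Jaccard index of covered bases. Single values of 2 WT and 2 KO mice were compared by a two-sided exact permutation test, which has 6 labelings and cannot give a p below 0.333. As a reference for WT-only and KO-only counts, the other 2 splits of the 4 libraries into pairs, each holding 1 WT and 1 KO, were counted by the same rule.

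The 15 gene lists were fixed before the data were examined: hematopoietic stem and progenitor regulators, erythroid and megakaryocyte genes, granulocyte and monocyte genes, B lymphoid genes, T and NK lymphoid genes, stromal and endothelial genes, Hox genes, non-Hox developmental transcription factors, Polycomb genes and H3K27 demethylases, Integrator subunits, cyclin-dependent kinase inhibitors with p53 targets and apoptosis genes, interferon-stimulated genes, bivalent signalling genes, ubiquitously expressed genes and replication-dependent histone genes (a list that also holds H1f0, H1f8 and H1f10, which are not replication-dependent). The list of Integrator subunits also held Nabp1, Nabp2 and Inip, which are partners of Ints3 in another complex. Of the 515 names written, 513 matched the table. For each list, the share of WT-only genes among genes with a peak in both WT libraries was compared with that of all other such genes by a two-sided Fisher's exact test, and the share of KO-only genes among genes with no peak in WT likewise, where at least 3 members could enter. This made 45 tests, adjusted together by the method of Benjamini and Hochberg. Genes are not independent replicates, so these tests compare the libraries at hand. Covered bases within 5 kb of the gene ends were averaged over each list and library.

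Named genes followed a rule fixed at the same time. For each mark it took the 10 WT-only and the 10 KO-only genes with the best mean percentile of their strongest peak by −log10 q, and up to 4 members of each list per class, with Ints11 first. A gene that this rule named is not reported here. Alternatives planned in advance were peaks with −log10 q of at least 5 or 10, the same number of peaks in each library, autosomes alone, a merging gap of 1000 bp, coverage of at least 50% of a region, windows of 1 and 5 kb (2 kb for the list averages), and leaving out each library. Added after seeing the data were the same covered length in each library, a peak anywhere over the gene, and H3K4me3 at a lone end taken as the start.

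Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The steps were tested on simulated data. The pileup was recovered for 100% of 2000 simulated peaks. Of 200 regions removed from both KO libraries in a copy of the WT_407 list, 180 were called WT only for H3K27me3 and 177 for H3K4me3, with a random loss of peaks in every library that made 28 and 71 other regions WT only. In H3K4me3 calls, the interferon-stimulated list with 50% of its genes removed, against 10% of others, passed the list test in 99 of 100 simulations. In these, 2 other lists also passed, and no list passed in 100 simulations without a difference. Genes were removed at random and not by peak strength. That list had 26 eligible genes for H3K4me3 and 3 for H3K27me3, so this pass rate does not carry over to H3K27me3. Jaccard indices equalled those of bedtools 2.31.1.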

Results

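The data were 8 lists of peaks for H3K27me3, the histone mark of Polycomb silencing, and H3K4me3, the mark of active or poised promoters. They came from lineage-negative, cKit-positive bone marrow cells of 2 WT mice (WT_407 and WT_409) and 2 Ints11 conditional knockout (KO) mice (KO_399 and KO_401), 4 days after poly(I:C). The H3K27me3 lists held 11930 peaks in WT_407, 9838 in WT_409, 6542 in KO_399 and 7653 in KO_401. The H3K4me3 lists held 25145, 26279, 27676 and 25090 peaks in the same order. H3K27me3 peaks covered 34.5, 31.5, 15.2 and 23.1 Mb, and H3K4me3 peaks 37.0, 38.6, 44.5 and 36.7 Mb. The series design gives 2 mice per genotype, and the 2 numbers of each genotype are read here as these mice. With 2 per genotype, no exact permutation test can give a p below 0.333.

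Ints11 itself lies on chromosome 4 from 155869547 to 155889103 (mm10). No library had an H3K27me3 peak within 2 kb of its ends. An H3K4me3 peak covered its lower end in all 4 libraries, with a fold given by the authors of 46.1 and 47.4 in WT_407 and WT_409 and of 67.2 and 71.7 in KO_399 and KO_401. This checks no label, because the promoter need not lie in the deleted part of the gene.

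The first comparison asked how the loss of Ints11 changed the distribution of H3K27me3. Developmental genes carried the mark in all 4 libraries, whereas weaker sites near genes such as Hba-a2, Col1a2, Rtp4 and Lefty1 had a peak in WT only. H3K27me3 covered 33.0 ± 2.09 Mb (SD, n = 2) in WT and 19.1 ± 5.64 Mb (SD, n = 2) in KO, or 58.0% of WT. Of 7371 regions present in both WT libraries, 1517 (20.6%) were in neither KO library and 4388 (59.5%) were in all 4, while 1 region was in both KO and neither WT library. At gene level, 419 genes were WT only, none was KO only, and 3481 had the mark in all 4 libraries.

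The number of H3K27me3 peaks was 10884 ± 1479 in WT and 7098 ± 786 in KO (SD, n = 2 each). Both differences exceeded the spread between mice, and both gave the smallest possible value of the exact permutation test (p = 0.333, n = 2 each). Median peak widths did not separate the genotypes, at 1891.5 bp in WT_407, 2275 bp in WT_409, 1790 bp in KO_399 and 2341 bp in KO_401 (exact permutation p = 1, n = 2 each). The 2 other splits of the libraries gave at most 128 regions and 55 genes in 1 pair only. The Jaccard index averaged 0.675 within genotypes (0.723 between the WT mice and 0.626 between the KO mice) and 0.559 between genotypes, a difference of 0.116 (0.0427, 0.0909, 0.0623 and 0.266 without WT_407, WT_409, KO_399 or KO_401). KO_401 overlapped WT_407 (0.633) and WT_409 (0.689) more than KO_399. Of the 4388 regions held by all 4 libraries, 3498 (79.7%) had fewer covered bases in both KO than in both WT libraries and none had more. Exchangeable libraries give 16.7% for each direction on average. A single split can lie far from this share, since the regions of a library are not independent. The mean covered length of the 4388 regions was 5674 ± 102 bp in WT and 4071 ± 911 bp in KO (SD, n = 2 each, exact permutation p = 0.333). The share of peak summits farther than 2 kb from a gene end and outside genes was 30.4 ± 3.36% in WT and 20.9 ± 2.01% in KO (SD, n = 2 each, exact permutation p = 0.333).

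**Figure D1:**
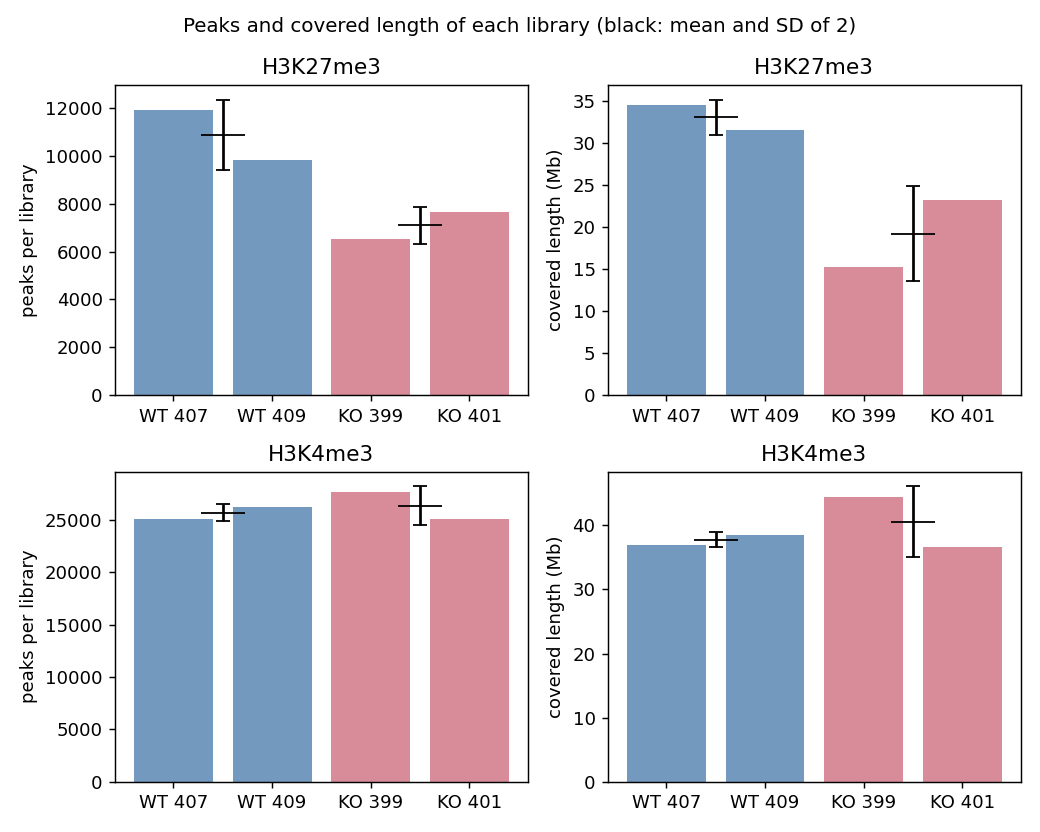
Peaks per library (left) and covered length in Mb (right) for H3K27me3 (top) and H3K4me3 (bottom), with a bar for each library, WT in blue and KO in red, and the mean and SD of the 2 mice of a genotype in black. H3K27me3 covered 34.5 and 31.5 Mb in the WT libraries and 15.2 and 23.1 Mb in the KO libraries, whereas the H3K4me3 values of the genotypes overlapped.

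The regions that were WT only were the weak ones. By −log10 q, their strongest peaks had a median percentile of 34.8 within the WT_407 list and 23.5 within the WT_409 list, against 81.3 and 77.0 for regions in all 4 libraries. Their median widths were 1440 and 1235 bp, against 4566 and 4393 bp. With the regions of both WT libraries ranked by this strength, 1282 of the weakest 1845 (69.5%) were WT only and none of the strongest 1842. The counts depended on how the lists were made equal. With the same number of peaks in each library, 376 regions were WT only and 5 KO only (at most 183 in the other splits), and with the same covered length, which leaves few but long peaks in WT, 1 was WT only and 535 were KO only. Without WT_407, WT_409, KO_399 or KO_401, when fewer libraries have to agree, 3324, 5263, 1621 and 2906 regions were WT only and 11, 12, 98 and 7 were KO only.

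The transcription factors of embryonic development carried H3K27me3 in every library. The list of 98 non-Hox developmental factors also held the signalling proteins Wnt1, Bmp4 and Shh. All 98 genes, among them Dlx2, Tbx2 and Foxc1, had H3K27me3 in all 4 libraries. None was WT only, against 419 of 4561 other genes (9.19%), the single list of the 45 tests to pass (Fisher's exact test, adjusted p = 0.00937, and 0.00229 adjusted over the H3K27me3 WT-only tests alone). These genes had strong peaks in WT. A peak in all 4 libraries does not mean an unchanged length. Covered bases within 5 kb were fewer in both KO than in both WT libraries at 75 of the 98 genes (76.5%). This held for 4131 of 6044 other genes (68.3%), with no difference past the threshold (Fisher's exact test, adjusted p = 0.863, chosen after seeing the data). The call was lost with the same number of peaks or the same covered length in each library (Fisher's exact test, adjusted p = 1 for both). Over all genes, 172 and 17 were then WT only, so the lost call does not show a change at the listed genes. Without KO_401, 3 lists passed. Of the 39 Hox genes, which specify position along the body axis, 36 had the mark in all 4 libraries and none was WT only. The peak at Hoxd10 was 69159 bp wide in WT_407, 73279 bp in WT_409, 32172 bp in KO_399 and 63414 bp in KO_401. Of the 40 bivalent signalling genes (WNT, BMP, FGF and Hedgehog pathways), 38 had H3K27me3 in all 4, and Lefty1, a Nodal antagonist, was WT only with 609 and 1265 bp in WT_407 and WT_409 and none in KO.

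Covered length around genes was lower in both KO than in both WT libraries for 12 of the 15 lists and higher for none, each with the smallest possible exact permutation p of 0.333. With the same covered length in each library, 3 lists were lower in both KO libraries. Over all protein-coding genes it was 1151 ± 16.6 bp per gene in WT and 744 ± 197 bp in KO (SD, n = 2 each), or 64.6%. The Hox genes stood at 88.9% of WT, the other developmental factors at 87.2%, the bivalent signalling genes at 75.3% and the stem and progenitor regulators at 74.7%. The windows cap these values where a domain is longer than the window, as at Hoxd10, Hoxd11 and Hoxd12, so the share kept at Hox and developmental genes is partly set by the window. Among the stem and progenitor regulators, 12 of 30 had the mark in all 4 libraries and none was WT only. Gata2, a transcription factor that stem cells need, had 12499 and 13055 bp in WT_407 and WT_409, and 9700 and 11210 bp in KO_399 and KO_401. Hoxa9, a homeobox factor of progenitors, had 14274 bp, its full window, in all libraries but KO_399 (11276 bp).

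The erythroid and megakaryocyte list had the mark in all 4 libraries at 2 of 22 genes (Zfpm1 and Epor), and the alpha-globin genes Hba-a1 (955 bp within 5 kb in KO_401) and Hba-a2 were WT only. These neighbouring copies are nearly identical in sequence, so reads cannot be placed on either copy with certainty. The mark was in all 4 libraries at 3 of 22 granulocyte and monocyte genes (such as Irf8), 2 of 16 B lymphoid genes (Pax5 and Ebf1), 6 of 20 T and NK lymphoid genes (such as Gata3 and Tcf7) and 6 of 20 stromal and endothelial genes, where Col1a2, a collagen gene, was WT only. Of the 34 Polycomb genes and H3K27 demethylases, 6 had it in all 4, including Bmi1 and Cbx8. Pcgf1, a subunit of a variant of Polycomb complex 1, was WT only within 2 kb, and within 5 kb it had 7709, 7667, 2054 and 4393 bp in WT_407, WT_409, KO_399 and KO_401. Ints3 was the only 1 of the 18 genes of the Integrator list with the mark in all 4. Of the 67 histone genes 2 had it in all 4, namely H1f0 and H1f10, which are not replication-dependent, and of the 28 ubiquitously expressed genes none had it in any library.

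Of the 31 cyclin-dependent kinase inhibitors, p53 targets and apoptosis genes, 5 had H3K27me3 in all 4 libraries, including the cell-cycle inhibitors Cdkn2a, Cdkn2b and Cdkn1c. The p53 targets Cdkn1a, a cell-cycle inhibitor, and Pmaip1, a cell-death gene, were WT only within 2 kb of their ends, 2 of 10 eligible against 417 of 4649 other genes (Fisher's exact test, adjusted p = 1). Cdkn1a had 2322 and 2760 bp within 5 kb in WT_407 and WT_409, none in KO_399 and 1886 bp in KO_401, and Pmaip1 had 2120, 3689, 0 and 530 bp in the same order. Of the 28 interferon-stimulated genes none had the mark in all 4, and Rtp4 was WT only with 1955 and 805 bp in WT.

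The 10 WT-only genes with the strongest WT peaks were Troap, Bsg, Klhl22, Ap1s1, Shkbp1, Mpg, Fam178b, Tjap1, Gramd1a and Slit1. At all 10 the WT domain reached into the 2 kb window and the KO peaks ended short of it. Both KO libraries had peaks within 5 kb, from 1273 bp (KO_399, Troap) to 2961 bp (KO_401, Shkbp1). Of the 419 WT-only genes, 354 (84.5%) had no KO peak within 5 kb. The strongest of these, chosen after their values were seen, included Acvr2a, an activin receptor, on chromosome 2 from 48814109 to 48903264 (1891 and 3797 bp in WT), Nnmt, nicotinamide N-methyltransferase (1958 and 2149 bp), and Serpine2, a protease inhibitor (1688 and 2672 bp). With the same number of peaks in each library, 172 genes were WT only and 2 KO only, and with the same covered length 17 and 393. Without WT_407, WT_409 or KO_401, 730, 734 and 1138 genes were WT only, and without KO_399, 9 were KO only.

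**Figure D2:**
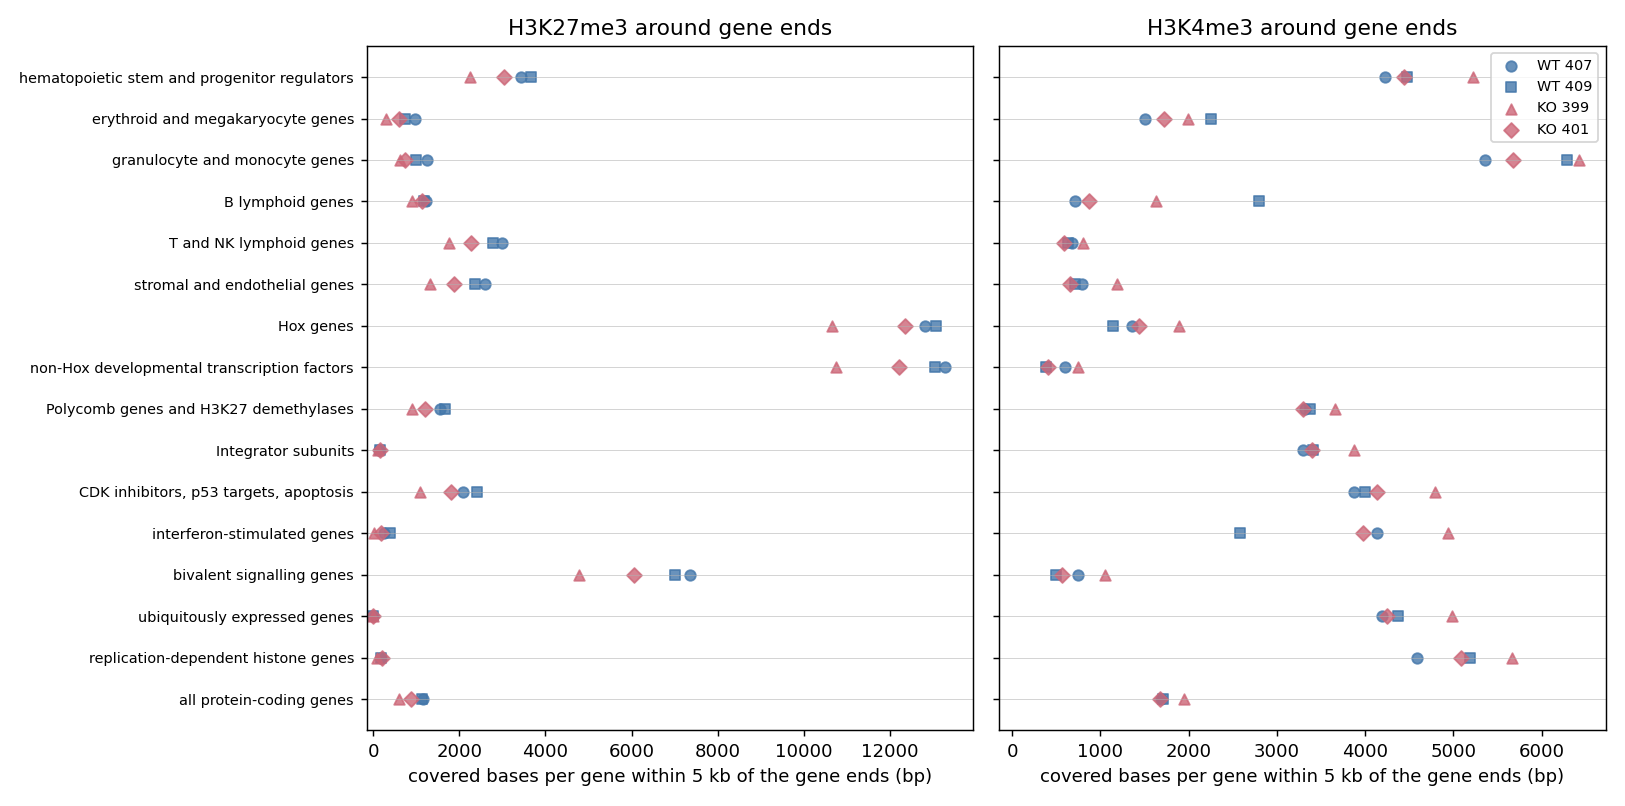
Covered bases per gene (bp) within 5 kb of the gene ends for H3K27me3 (left) and H3K4me3 (right), averaged over each gene list, with a symbol for each library, WT in blue and KO in red. For H3K27me3 both KO libraries lay below both WT libraries in 12 of 15 lists, and for H3K4me3 the interferon-stimulated genes were lowest in WT_409 (2579 bp) and the B lymphoid genes highest there (2796 bp).

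The second comparison asked the same of H3K4me3. The p53 target Cdkn1a, on chromosome 17 from 29090979 to 29100722, had an H3K4me3 peak within 2 kb of an end in KO only. That peak was 6605 bp wide in KO_399 and 406 bp in KO_401, and within 5 kb the gene had 2575 and 2611 bp in WT_407 and WT_409 and 3228 bp in KO_401. The covered length of H3K4me3 did not separate the genotypes, at 37.8 ± 1.12 Mb in WT and 40.6 ± 5.50 Mb in KO (SD, n = 2 each, exact permutation p = 1). There were 25712 ± 802 peaks in WT and 26383 ± 1829 in KO (SD, n = 2 each, exact permutation p = 1). Of 13759 genes with a peak in any library, 12650 had it in all 4, 18 were WT only and 65 were KO only.

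Genotype did not order the H3K4me3 libraries. The Jaccard index was 0.788 within and 0.795 between genotypes. There were 308 WT-only and 623 KO-only regions, whereas the other splits reached 751 and 848 regions in 1 pair only. For genes, the other splits reached 154 and 70. KO_399 had the most peaks and 261 genes of its own. It also had the most background reads per position (2.65, against 2.23 in WT_407, 1.94 in WT_409 and 1.93 in KO_401). Whether depth made its extra peaks was not tested. Without KO_399 the difference in peak number (KO minus WT) was -622 and that in covered length -1.11 Mb. Without WT_407, WT_409, KO_399 or KO_401, 1721, 1070, 1188 and 517 regions were WT only and 1360, 1716, 1238 and 2815 KO only. In the same order, 89, 90, 141 and 34 genes were WT only and 225, 136, 80 and 326 KO only.

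The 10 KO-only genes with the strongest peaks were Pcolce, 4430402I18Rik, Cdkn1a, Apobec2, Gm52481, Atp8b5, Myct1, Inha, Asb4 and Slc2a10. Myct1 had 1272 and 1164 bp of H3K4me3 within 5 kb in WT_407 and WT_409, and 3232 and 2571 bp in KO_399 and KO_401. Inha, an inhibin subunit, had none in WT, and 1123 and 873 bp in KO. The list members among the KO-only genes were Cdkn1a, Slamf1 (CD150, a surface marker of stem cells), Lck (a T cell kinase) and Wnt10a. Slamf1 had 1170 bp in KO_399 and 272 bp in KO_401. The strongest WT-only genes included Nedd4l, Pxt1, Gm10479, Gm38538, Gm10476, Gm3993, Gm40862, Gm9257 and Gsg1l. The 6 Gm genes are predicted genes that lie together on chromosome 12, and reads from families of similar copies cannot be placed with certainty. No list passed the test of KO-only or WT-only genes for H3K4me3 (45 tests over both marks, and none at an unadjusted p under 0.05), and without WT_407 and without KO_401 there were 4 and 3 such lists.

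H3K4me3 was in all 4 libraries at most genes of 8 lists, namely 26 of 30 stem and progenitor regulators, 21 of 22 granulocyte and monocyte genes, 33 of 34 Polycomb genes and H3K27 demethylases, 18 of 18 Integrator subunits, 29 of 31 cyclin-dependent kinase inhibitor, p53 target and apoptosis genes, 26 of 28 interferon-stimulated genes, 27 of 28 ubiquitously expressed genes and 65 of 67 histone genes. Lower counts were found for erythroid and megakaryocyte genes (9 of 22), B lymphoid genes (5 of 16), T and NK lymphoid genes (7 of 20), stromal and endothelial genes (7 of 20), Hox genes (16 of 39), other developmental factors (19 of 98) and bivalent signalling genes (12 of 40).

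Covered length was higher in both KO than in both WT libraries for 2 lists and lower for none. The Hox genes had 1250 ± 155 bp per gene in WT and 1663 ± 327 bp in KO, and the cyclin-dependent kinase inhibitors, p53 targets and apoptosis genes had 3933 ± 88.1 and 4463 ± 467 bp (SD, n = 2 each, exact permutation p = 0.333 for both). Hoxa9 had 8985, 6579, 11324 and 10004 bp in WT_407, WT_409, KO_399 and KO_401. Of the 31 cyclin-dependent kinase inhibitor, p53 target and apoptosis genes, 17 were longer in both KO libraries, against 23.3% of all genes with H3K4me3. The following genes were chosen after their values were seen. The p53 targets Mdm2 (2953, 3162, 5814 and 4626 bp in the same order), Phlda3 (946, 923, 2695 and 2095 bp) and Ccng1 (1661, 1621, 2892 and 2096 bp) had more H3K4me3 in both KO libraries, and so did Gata2 (5191, 5121, 7993 and 6986 bp). Over all genes the values were 1694 ± 18.9 bp in WT and 1810 ± 195 bp in KO (SD, n = 2 each, exact permutation p = 1). Without WT_407, WT_409 or KO_401, 5, 9 and 13 lists were higher in KO.

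WT_409 had the highest average of the 4 libraries at B lymphoid and erythroid genes and the lowest at interferon-stimulated genes. Its averages lay within the range of the others at T and NK lymphoid, stromal and endothelial, and granulocyte and monocyte genes. By single genes, WT_409 was longest at 9 of 22 granulocyte and monocyte genes (40.9%, against 13.5% of all genes) and shortest at 5. It was also lowest at Hox genes, other developmental factors (377 bp) and bivalent signalling genes (492 bp). B lymphoid genes had 2796 bp of H3K4me3 per gene in WT_409, against 715 bp in WT_407, 1633 bp in KO_399 and 872 bp in KO_401. Peaks lay at 13 of these 16 genes in WT_409, 11 in KO_399, 5 in WT_407 and 7 in KO_401. Pax5, the B cell commitment factor, had 3869 bp in WT_409, 362 bp in KO_399 and none in the other two, and Il7r had 2855 bp in WT_409 alone. The erythroid genes Hbb-bs (beta-globin, 1026 bp) and Slc4a1 (band 3, 1079 bp) also had H3K4me3 in WT_409 alone. Interferon-stimulated genes had 4136, 2579, 4938 and 3972 bp per gene in WT_407, WT_409, KO_399 and KO_401, so that the means of 3357 ± 1101 bp in WT and 4455 ± 683 bp in KO (SD, n = 2 each) differed by less than the SD of WT and the ranges overlapped (exact permutation p = 0.667, n = 2 each). Ifit1, an antiviral gene, had 3127, 881, 4805 and 3865 bp in the same order.

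**Figure D3:**
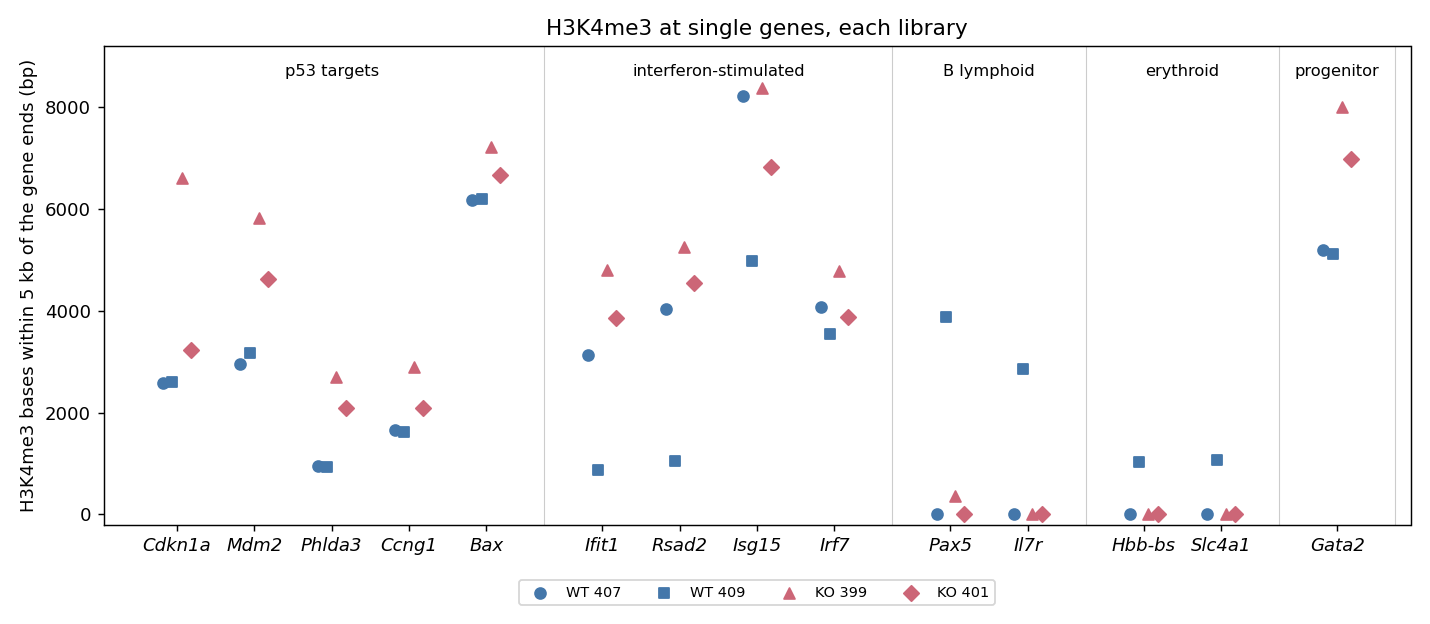
H3K4me3 bases (bp) within 5 kb of the gene ends for single genes, with a symbol for each library, WT in blue and KO in red. Both KO libraries lay above both WT libraries at Cdkn1a, Mdm2, Phlda3, Ccng1, Bax and Gata2, and WT_409 lay below the other libraries at Ifit1, Rsad2, Isg15 and Irf7 and above them at Pax5, Il7r, Hbb-bs and Slc4a1.

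The third comparison joined the marks, to ask whether genes that lacked H3K27me3 in KO gained H3K4me3. Of the 419 genes with H3K27me3 in WT only, 3 had H3K4me3 in both KO and neither WT library, namely Cdkn1a, Crybb1 (a lens crystallin) and Taok1 (a kinase). Only genes with no H3K4me3 peak within 2 kb of an end in either WT library can gain such a peak. Among them, 3 of 150 (2%) of the genes with H3K27me3 in WT only gained one, against 22 of 1080 (2.04%) of the genes with H3K27me3 in all 4 libraries (Fisher's exact test, p = 1, chosen after seeing the data). Within 5 kb, Cdkn1a and Taok1 had H3K4me3 in both WT libraries, and Cdkn1a kept H3K27me3 in KO_401. Taok1 had 190 and 233 bp of H3K4me3 within 5 kb in WT_407 and WT_409, and 1111 and 403 bp in KO_399 and KO_401. H3K4me3 was in both KO libraries at 251 of the 419 genes (59.9%) and 2159 of the 3481 (62.0%), with no difference past the threshold (Fisher's exact test, adjusted p = 0.932 over 5 such tests). It was in no library at 137 (32.7%) and 893 (25.7%), a difference past the threshold (Fisher's exact test, adjusted p = 0.0137). With the same number of peaks in each library the difference shrank to 2.49 percentage points and the call was lost (Fisher's exact test, p = 0.486). With the same covered length the difference was larger (15.2 points), but 17 WT-only genes were left and the call was lost too (Fisher's exact test, p = 0.168). These shares depended on single libraries. For H3K4me3 in both KO libraries, the difference (WT-only genes minus genes with H3K27me3 in all 4) was 9.73 percentage points without H3K27me3 of WT_407 (Fisher's exact test, p = 5.6e-07) and -10.7 without that of WT_409 (Fisher's exact test, p = 1.0e-07). It was 1.60 points without H3K27me3 of KO_401 (Fisher's exact test, p = 0.342) and -6.67 points without H3K4me3 of KO_401 (Fisher's exact test, p = 0.00493). For H3K4me3 in no library, it was -2.63 and 17.4 points without H3K27me3 of WT_407 and of WT_409.

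Genes with both marks within 2 kb of an end, not necessarily the same end, numbered 3275 and 3254 in WT_407 and WT_409, and 2556 and 2733 in KO_399 and KO_401. The means were 3265 ± 14.8 in WT and 2645 ± 125 in KO (SD, n = 2 each, exact permutation p = 0.333), a difference (KO minus WT) of -620. It was -329.5 with the same number of peaks in each library and 393 with the same covered length. Genes with H3K27me3 alone numbered 1759 ± 28.3 and 1277 ± 419, and genes with H3K4me3 alone 9848 ± 107 and 10628 ± 524 (SD, n = 2 each, exact permutation p = 0.333 for both). The genes with both marks were 65.0 ± 0.47% of genes with H3K27me3 in WT and 67.9 ± 6.22% in KO (SD, n = 2 each, exact permutation p = 1).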

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

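The same covered length in each library, a peak anywhere over the gene, and a lone end with H3K4me3 taken as the start were chosen after seeing the data, as were the tests of list members by length and the alternatives for developmental factors and for genes with H3K4me3 in no library. Over all results and alternatives, 191 values were the same, 59 moved, 5 lost and 2 gained their call, and 11 turned. Differences were the same when they kept their direction and, where tested, their side of the threshold. Counts without a test were the same within a fixed ratio of the main value, and moved otherwise. A Jaccard difference moved when it changed by at least the SD of the between-genotype indices. The lower number and covered length of H3K27me3 peaks in KO kept its direction under every alternative but the same covered length, which turned the number of peaks. Autosomes alone, windows of 1 kb, a gap of 1000 bp and lists read within 2 kb changed no call. Peaks with −log10 q of at least 5 did not differ from the deposited lists, as all peaks were above it.

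With −log10 q of at least 10, there were 0 KO-only H3K27me3 regions, 169 WT-only and 391 KO-only H3K4me3 regions, 39 KO-only H3K4me3 genes, and 4 lists with more H3K4me3 in both KO libraries. Coverage of 50% of a region left 0 KO-only H3K27me3 regions. Windows of 5 kb gave 1 KO-only H3K27me3 gene, and the difference between genes with H3K27me3 in WT only and in all 4 libraries in the share with H3K4me3 in both KO libraries turned to 0.0797 percentage points. The cause was not tested.

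With the same number of peaks in each library, H3K27me3 gave 376 WT-only and 5 KO-only regions, 172 WT-only and 2 KO-only genes, and 0 lists past the threshold. This follows from the construction, which drops the weak peaks of WT. Peak number itself is fixed by this alternative and has no value, and covered length has none under the next.

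The same covered length turned several results. For H3K27me3 this follows from the construction, as long strong domains fill the length in WT with few peaks, and for H3K4me3 the cause was not tested. For H3K27me3, the difference in peak number (KO minus WT) was 2688, 1 region was WT only and 535 KO only, 17 genes were WT only and 393 KO only, 3 lists were lower in both KO libraries, and 2 lists passed the test. For H3K4me3, the difference in peak number was -2319.5, 487 regions were WT only and 15 KO only, 54 genes were WT only and 5 KO only, and 4 lists were higher. The genes with both marks differed by 393, and the share with H3K4me3 in both KO libraries by 1.14 percentage points.

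Leaving out each library in turn leaves 1 library in a genotype, so fewer libraries have to agree and counts grow by construction. For H3K27me3, WT-only regions ranged from 1621 to 5263 and KO-only regions from 7 to 98, WT-only genes from 459 to 1138 and KO-only genes from 1 to 9. The Jaccard difference ranged from 0.0427 to 0.266, and the lists past the threshold from 1 to 3. For H3K4me3, WT-only regions ranged from 517 to 1721 and KO-only regions from 1238 to 2815, WT-only genes from 34 to 141 and KO-only genes from 80 to 326. The difference in peak number ranged from -622 to 1964, in covered length from -1.11 to 6.68 Mb, and in the Jaccard index from -0.0225 to 0.0126. Lists with more H3K4me3 in both KO libraries ranged from 2 to 13, and lists past the threshold from 0 to 4. At genes with H3K27me3 in WT only, the difference in the share with H3K4me3 in both KO libraries ranged from -10.7 to 9.73 percentage points, and in the share with H3K4me3 in no library from -2.63 to 17.4. The cause of these turns was not tested.

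No paired analysis was possible because the WT and KO groups share no number, and the numbers shared by the marks join libraries of the same genotype. The alternative of the most 5-prime transcript alone was not run, since the gene table holds no strand and no transcripts. Depth limits what is called at a fold of 5, and sites under that fold in a library count as absent here.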

Other observations

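Leaving out each library was planned and the 2 tests on random matched lists were written before their results were seen, but the tests of list members by length and the others below were chosen after. The histone genes had the shortest H3K4me3 of the 4 libraries in WT_407 at 58 of 65 genes, against 33.4% of all genes with H3K4me3. KO_399 had the longest H3K4me3 at 54 of these 65, and at 72.5% of all genes. The list averaged 4592 bp per gene in WT_407, 5190 bp in WT_409, 5665 bp in KO_399 and 5082 bp in KO_401. On chromosome 12, 15 of the 92 H3K4me3 regions between 20 and 30 Mb were WT only, the most of any 10 Mb stretch, and 308 of 30534 were so over the genome.

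Both KO libraries had fewer H3K27me3 peaks over less of the genome. The background reads per position were higher in KO by 0.365 on average and in both KO libraries. They argue against shallower KO libraries only as far as background follows depth. Fragment length and any scaling to input also enter this value and are not known, so shallower KO libraries are not excluded. The direction did not rest on a single KO library. The difference in covered length (KO minus WT) was -9.88 Mb with KO_399 left out and -17.9 Mb with KO_401 left out. Each of these values rests on a single KO mouse. The KO libraries themselves differed, with 15.2 Mb in KO_399 and 23.1 Mb in KO_401, so the size of the difference depended on the library. A lower yield of the immunoprecipitation in KO, alike for all regions, cannot be told apart from a loss of the mark in the cells: with equal peak numbers 376 regions were WT only (183 at most in other splits), with equal covered length the direction turned, and no spike-in is named in the labels. The absence of WT-only developmental factors may follow from their strong H3K27me3, since 46.2% of 10000 random lists matched on WT strength also held no WT-only gene.

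At the cyclin-dependent kinase inhibitor, p53 target and apoptosis genes, H3K4me3 was longer in both KO than in both WT libraries at 17 of 31 genes (54.8%), against 3375 of 14549 other genes (23.2%). Exchangeable libraries would give 16.7%, but the splits that mix the genotypes reached 35.4% of other genes. It was the 1 of 52 tests of lists by length to pass (Fisher's exact test, adjusted p = 0.00738), but each of the 2 other splits, which mix the genotypes, passed 2 tests (interferon-stimulated and histone genes in 1 split, and non-Hox developmental factors and interferon-stimulated genes in the other), so a single passing list is no more than splits without genotype gave. The broad peaks of KO_399 cannot be told apart from an effect of genotype, since the 17 genes found without KO_399 (Fisher's exact test, unadjusted p = 0.00052) follow from how the list was picked, and without KO_401 the unadjusted p was 0.676 (25 genes), against 8.3e-05 to 0.016 under the other alternatives. Random lists matched on the length of H3K4me3 in WT held 7.60 such genes on average, and 0.04% of 10000 held as many as 17. The list was picked for its high count in the same libraries, so a low share was likely beforehand. The draws also treat genes as independent. This share therefore cannot decide whether the length of H3K4me3 in WT plays a part. Whether the difference goes with the loss of Ints11 or with single libraries stays open, and no biological explanation was tested.

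In WT_409, H3K4me3 was the shortest of the 4 libraries at 26 of 28 interferon-stimulated genes, against 26.1% of all genes. KO_401, with as few background reads (1.93 against 1.94), was shortest at 2 of the 28. This cannot decide on a shallow library, because with WT_409 shortest at 26, KO_401 could be shortest at no more than 2. By average, KO_401 had 3972 bp per gene there, against 4136 bp in WT_407 and 2579 bp in WT_409. Such depth alone thus need not shorten the mark at these genes. Cells of other lineages in the sample are a possible explanation. H3K4me3 was longest in WT_409 at 12 of 15 B lymphoid and 12 of 20 erythroid and megakaryocyte genes with the mark. It was longest there at 9 of 22 granulocyte and monocyte genes and at 13.5% of all genes. However, 5 of the 16 B lymphoid and 9 of the 22 erythroid genes had H3K4me3 in all 4 libraries. The sort for lineage-negative cells, which the series design names and the sample labels do not, should remove mature B and red cells, and dilution by such cells stays open, because WT_409 was shortest at 46.7% of the stem and progenitor regulators, between the share of all genes and that of the interferon-stimulated genes, while their average there (4472 bp) was above that in WT_407 (4230 bp) and KO_401 (4442 bp), which runs against dilution. A weaker response to poly(I:C) in this mouse stays open as well, and no biological explanation was tested.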
